A study of Mus musculus with 9 samples.

How the data were processed

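Mononuclear phagocytes of 3 populations were sorted from the Peyer's patches of female wild-type C57BL/6 mice aged 6 to 8 weeks, per the labels. Each population was measured on 3 arrays, and the series' design text describes 3 independent experiments. The labels do not say how many mice gave each sample. Total RNA was isolated with a Qiagen micro column kit, and 5 to 17 ng was amplified with the NuGEN Ovation Pico system and labelled with biotin, per the labels' protocols. The arrays were Affymetrix whole-transcript arrays, on which probes spread along a gene are summarised as a transcript cluster. Affymetrix Expression Console 1.1 and RMA (robust multi-array averaging) are named in the submitters' processing notes, and their settings and the genome build are not given in the sources used here. The deposited values are intensities on a linear scale, normalized by the authors and rounded to 0.1, and they ran from 4.2 to 15241.5 over 35556 transcript clusters with 0 missing values. No detection call per cluster was used here, so a low intensity was not separated from background, and a population mean under the median of all genes is not taken as shown to exceed it. Differences from such a mean are bounds, a choice made after the results were seen, and none is given where both means lay under that median. Tests and list medians used the log2 values with no such floor. The precision of each value is limited by the number of arrays.

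From these deposited intensities, log2 values were computed first, with no further normalization. Gene symbols came from the platform annotation paired with the clusters. In it, 21789 clusters had 1 gene symbol, 1621 had several and 12146 were not listed, and only clusters with 1 symbol were named. Of these, 21698 matched a mouse gene of the GRCm38.p6 gene table by Entrez identifier, and 0 symbols changed. For the 998 genes with more than 1 cluster, the cluster with the highest mean over the 9 arrays was used, which left 19938 genes. No dim gene was removed. No 2 arrays held the same values: Pearson's r of log2 values across clusters, which are not independent replicates, was at most 0.9907 within a population.

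One linear model over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3, so that the 3 populations shared an estimate of the spread, and limma's moderated test compared lysoDC with CD11b+ cDC, lysoMac with CD11b+ cDC and lysoMac with lysoDC. P-values were adjusted by the Benjamini-Hochberg method over the 19938 genes, and a gene passed at an adjusted p under 0.05. Standard errors are those of the moderated fit. A gene was counted as highest in a population when both comparisons passed and both log2 differences were at least 1. Before the data were examined, 36 gene lists were fixed: 20 for cell identity or function, 12 for other cell types that a sort could contain and 4 for RNA quality or stress. The lists held 7 to 38 measured genes, and of 751 planned members 676 were measured. Each list was tested with camera (a test in limma of whether a list's genes rank above or below the other genes), two-sided, with a preset correlation of 0.01, and the adjustment covered the 36 lists of a comparison. Camera with a correlation estimated from the arrays was run beside it. The preset correlation treats the genes of a list as nearly independent, so its small p-values do not measure the spread among 3 arrays.

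The genes named in the report were chosen by a rule fixed at the same time. It took the genes of the sort gate, and the 6 highest and 6 lowest log2 fold changes of each comparison among genes that passed, whose arrays did not overlap and whose higher mean lay above the median of all genes, leaving out provisional names and antigen receptor segments. It also took up to 3 passing members with the largest change per functional or quality list (2 with the smallest p where none passed), the most abundant member of each list of another cell type, and the 5 leading genes highest in each population. Where a list had at most 6 passing members, the rule allowed naming all of them but did not require it. Under that allowance Epcam, Cdh17, Gp2, Il7r, Klrk1 and Cd6 were chosen after their values were seen. So were Siglech, the 9 genes with opposite changes in the lyso populations and the markers used to test for epithelial and lymphocyte RNA.

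On simulated data with the spread of the real genes, for lysoDC against CD11b+ cDC over 19938 genes, the fit recovered 25 of 50 genes changed by 0.5 on the log2 scale, 41 of 50 changed by 1, and 50 of 50 changed by 2 or by 4. In that simulation 14 of 180 calls were false. Alternatives covered the replicate number as a fixed or random block, the prior variance (trend or robust), a filter on dim genes, repeated quantile normalization, median centring, array weights, other handling of several clusters per gene, all clusters tested, fits on 6 arrays, stricter thresholds, other list tests and leaving out each array. Leaving out all arrays numbered 1 was added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.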

Results

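Gene expression was measured in 3 phagocyte populations of the mouse Peyer's patch, the lymphoid follicles of the intestinal wall that sample gut antigens. Conventional dendritic cells of the CD11b+ type (CD11b+ cDC) were sorted as cells with high CD11c and MHC class II that were positive for CD172a and CD11b and negative for Bst2, CD8 and CD4. LysoDC, dendritic cells named for lysozyme, shared high CD11c and MHC class II and differed in high CD11b and in Bst2. LysoMac, the corresponding macrophages, were sorted with high CD11c and low MHC class II as cells positive for CD172a, CD11b, Bst2 and CD4. Each population had 3 arrays, and 19938 genes were compared. The first principal component held 69.9% of the variance and placed the CD11b+ cDC arrays at -57.27 to -60.59 and all 6 lyso arrays at 20.48 to 39.46. The second held 9.5% and placed the lysoDC arrays at 17.25 to 22.89 and the lysoMac arrays at -13.41 to -19.23.

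Transcripts of the sorted surface proteins followed the gates, which is a check of the labels and not a finding. Bst2 averaged 9.64 in CD11b+ cDC, 11.84 in lysoDC and 11.88 in lysoMac (log2 intensity, n = 3 each). Cd4 averaged 6.24 ± 0.42 (SD, n = 3) in CD11b+ cDC, 6.11 ± 0.58 in lysoDC and 11.43 ± 0.13 in lysoMac. Itgam, which encodes CD11b, was highest in lysoDC at 10.39 ± 0.06, against 8.19 in CD11b+ cDC and 9.21 ± 0.16 in lysoMac. H2-Ab1, of MHC class II, averaged 12.56 in CD11b+ cDC, 12.55 ± 0.05 in lysoDC and 10.64 ± 0.37 in lysoMac. Sirpa, which encodes CD172a, was higher in lysoDC by 0.90 and in lysoMac by 1.03 than in CD11b+ cDC. Itgax and Cd8a did not pass between either lyso population and CD11b+ cDC.

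**Figure D1:**
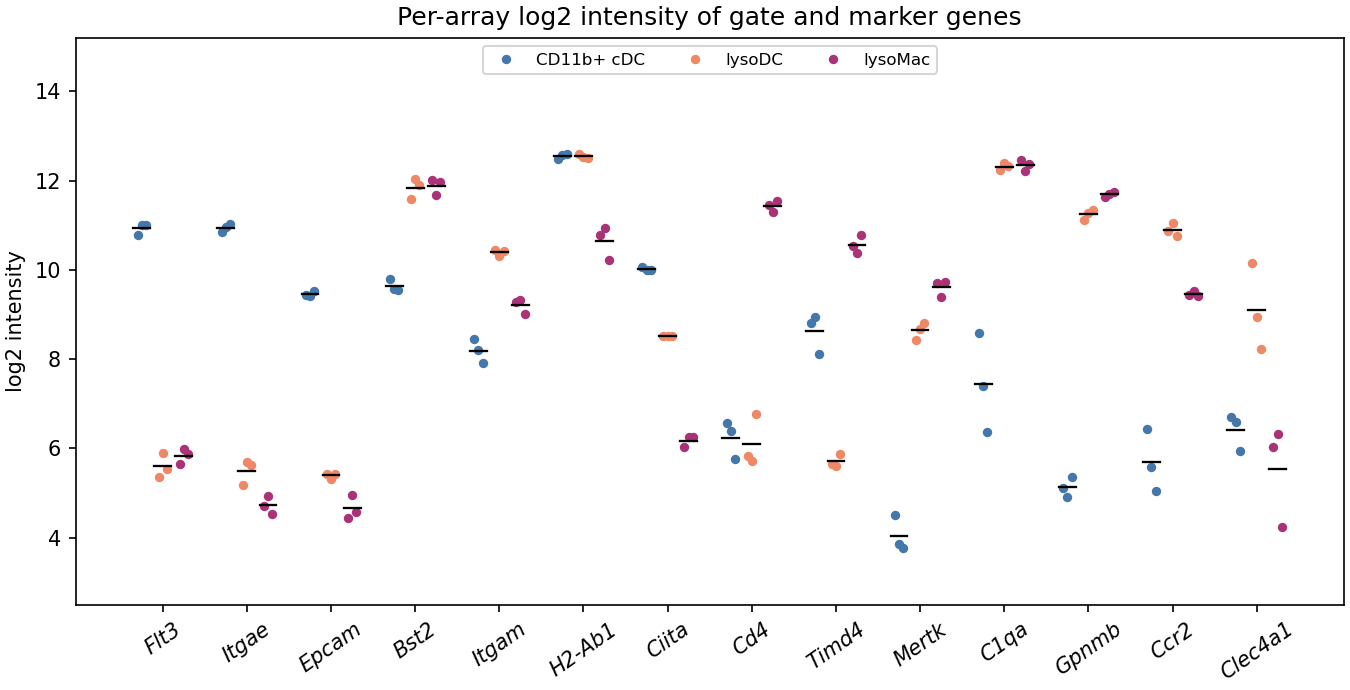
Log2 intensity (vertical axis) of 14 gate and marker genes (horizontal axis) on each of the 9 arrays, with points for arrays, colours for the 3 populations and black bars for group means (n = 3). Flt3, Itgae and Epcam were high on the 3 CD11b+ cDC arrays, Cd4 was high on the 3 lysoMac arrays, and Mertk, C1qa and Gpnmb were high on all 6 lyso arrays.

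The comparison of lysoDC with CD11b+ cDC asked how 2 populations that both carry dendritic cell surface markers differ in transcription. In lysoDC, most members of the macrophage core, lysosome and iron lists and 8 of 15 complement genes were higher, and most genes of the conventional dendritic cell list were lower. A population mean under the median of all genes, 5.66, was not shown to exceed background. Against such a mean only a bound is given, written as at least, with the arrays of the lower population that lay under that median raised to it. Gpnmb, a transmembrane glycoprotein (transcript cluster 10538187), averaged 11.25 ± 0.12 (SD, n = 3) in lysoDC against 5.13 ± 0.23, at least 47.9-fold higher (adjusted p = 2.62e-08). The other 5 increases taken by the naming rule were in Cp (at least 28.0-fold), the ferroxidase ceruloplasmin, in C5ar1 (at least 33.8-fold), the receptor for complement fragment C5a, in Ms4a4a (at least log2 4.64), in Mmp2 (at least 47.2-fold), a matrix metalloproteinase, and in Acod1 (52.5-fold), which makes the antimicrobial metabolite itaconate. The 6 decreases so taken were in Klri1 (at least 22.2-fold) and Klrd1 (43.9-fold), lectin-like receptors, P2ry10 (at least 12.9-fold), Pglyrp1 (45.9-fold), a peptidoglycan recognition protein, Itgae (at least 38.7-fold), which encodes CD103, and Flt3 (at least 36.6-fold), the receptor for the growth factor on which conventional dendritic cells depend. The lysoDC means of Klrd1 (5.70 ± 0.93 SD) and Pglyrp1 (5.76 ± 0.23) lay only just above that median, so their folds are little firmer than bounds.

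Of the 36 gene lists, 16 were shifted in lysoDC against CD11b+ cDC, 9 upward and 7 downward. With an estimated correlation 8 of them also passed, with adjusted p from 0.00152 (macrophage core) to 0.0482 (antimicrobial and type 2 dendritic cell genes). The macrophage core list had 31 of 36 members higher and 0 lower (median log2 change 1.68, camera adjusted p = 5.81e-31), among them the nucleic acid sensor Tlr7 (at least 13.6-fold), Mertk (at least 7.89-fold), a receptor for apoptotic cells, and the Fc receptor gene Fcgr3 (log2 4.39 ± 0.22 SE). In the lysosome list 27 of 38 members were higher and 1 lower (adjusted p = 9.48e-20). Atp6v0d2, a proton pump subunit, rose by at least 2.35 and the acid phosphatase Acp2 by 2.18, whereas the protease Lgmn fell by 2.60. Complement genes were higher for 8 of 15 members and lower for 0 (adjusted p = 3.06e-08). C1qa and C1qb, subunits of C1q, averaged 12.32 and 12.42 in lysoDC against 7.45 and 7.55. C1qa varied among the CD11b+ cDC arrays, from 6.37 to 8.58 (SD 1.11, against 0.08 in lysoDC). That list also holds Itgam, a gate gene. Of the iron and haem list, 11 of 15 members were higher and 1 lower (adjusted p = 2.84e-08), with Cp, the haem-degrading enzyme Hmox1 (3.00) and the transcription factor Spic (at least 2.58). The antimicrobial list had 8 of 19 higher and 2 lower (adjusted p = 0.000125), including the pore-forming Mpeg1 (2.76) and the lysozyme gene Lyz1, which averaged 13.33 ± 0.04 in lysoDC and 11.06 in CD11b+ cDC. Counts adjusted over the list alone (higher and lower) were 32 and 0 for macrophage core, 29 and 1 for lysosome, 8 and 0 for complement, 11 and 1 for iron and haem and 10 and 2 for antimicrobial genes.

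A further 4 lists were higher with the preset correlation alone. Interferon response genes were higher for 15 of 30 members and lower for 2, with Irf7 (2.73) and the antiviral gene Rsad2 (2.31) up and Ifitm1 down by log2 -2.38 (adjusted p = 0.149 with an estimated correlation). Matrix and remodelling genes were higher for 8 of 22 and lower for 4, with Mmp2, the protease inhibitor gene Timp2 (at least 3.98) and Adamdec1 (4.42), with adjusted p = 0.0864 for an estimated correlation. Lipid and cholesterol genes were higher for 8 of 20 and lower for 1, with Gpnmb, Apoe (3.84) and the oxysterol receptor Nr1h3 (2.72), and gave adjusted p = 0.127 with an estimated correlation. Pattern recognition genes were higher for 11 of 25 and lower for 5, with Clec4d (at least 4.51) and Clec4e (at least 4.33), C-type lectins, up and Clec12a down by at least 1.24, and gave adjusted p = 0.253 with an estimated correlation. When camera was run on ranks, the calls of the matrix (adjusted p = 0.0903), lipid (0.0903) and pattern recognition lists (0.107) ended. Adjusted over the list alone, the numbers higher and lower were 19 and 3 for interferon response, 10 and 5 for matrix, 8 and 2 for lipid and 13 and 6 for pattern recognition genes.

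The conventional dendritic cell core list was lower in lysoDC for 23 of 28 members and higher for 0 (median -1.95, adjusted p = 9.27e-24). The list of genes associated with type 2 conventional dendritic cells was lower for 8 of 11 and higher for 0 (adjusted p = 1.12e-07), with the lymphotoxin gene Ltb at -3.12, Cd209a lower by at least 2.72 and Mgl2 by at least 1.64. Immediate early genes, which cells induce within minutes of a stimulus, were lower for 14 of 18 and higher for 0 (adjusted p = 3.8e-13). Nr4a1 was at least 21.5-fold lower, Egr2 4.15-fold and Btg2 3.57-fold. These 3 lists also passed with an estimated correlation. Costimulation genes were lower for 7 of 20 and higher for 1, with Cd83 (-3.26) and Icosl (-3.21) down and Tnfsf9 lower by at least 1.97, and gave adjusted p = 0.254 with an estimated correlation. Ribosomal protein genes were lower for 4 of 20, led by Rpl14 (-0.86), and gave adjusted p = 0.169 with an estimated correlation. MHC class II genes were not shifted as a list (adjusted p = 0.241), although the transactivator Ciita (-1.49) and H2-Oa (-3.65) and H2-Ob (-2.93), chains of the DO modulator, fell. Proliferation genes were not shifted (2 of 29 higher, 2 lower, adjusted p = 0.648), with Bub1b at 1.67, Mcm4 at -1.21 and Mcm6 at -0.97. The numbers higher and lower, adjusted over the list alone, were 1 and 23 for the dendritic cell core, 0 and 8 for the type 2 list, 0 and 15 for immediate early, 3 and 8 for costimulation, 0 and 12 for ribosomal protein, 2 and 3 for MHC class II and 3 and 4 for proliferation genes.

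Markers of other cell types moved in part. Of 17 intestinal epithelial genes, 3 were lower in lysoDC and 0 higher, with adjusted p = 1.44e-05 for the list and 0.338 with an estimated correlation. Epcam, an adhesion molecule, averaged 9.46 ± 0.05 (SD, n = 3) in CD11b+ cDC and was at least 13.9-fold lower in lysoDC. Cdh17, a cadherin gene, averaged 8.11 ± 0.47 and was at least 5.44-fold lower, and Gp2 averaged 7.43 ± 0.26 and was at least 3.39-fold lower. The other 14 members, Fabp1 and Muc2 among them, did not pass, and on CD11b+ cDC replicate 1 these 14 exceeded the mean of replicates 2 and 3 by a median of 2.49. The median change of the list was -0.95 with all arrays, -0.13 without CD11b+ cDC replicate 1, -1.47 without replicate 2 and -1.54 without replicate 3. Of 12 NK and innate lymphoid genes, 4 were lower and 1 higher. The 4 included Klrd1, Klrk1 (-1.73) and Il7r, the interleukin-7 receptor, which fell by at least 2.27. That list gave adjusted p = 0.149 with an estimated correlation, and without CD11b+ cDC replicate 3 its camera adjusted p was 0.0551, and 0.14 on ranks. The B cell list (1 of 17 higher, 2 lower, adjusted p = 0.384) and the T cell list (3 of 13 higher, 1 lower, adjusted p = 0.17) were not shifted, but Cd79b (2.84), of the B cell receptor complex, and Cd6 (2.32) and Icos (1.70), T cell surface receptors, rose. Plasmacytoid dendritic cell genes (3 of 13 higher, 6 lower) and type 1 conventional dendritic cell genes (5 of 15 higher, 4 lower) were not shifted (camera adjusted p = 0.17 and 0.578). In lysoMac against CD11b+ cDC the counts were 3 and 6, and 5 and 5 (camera adjusted p = 0.276 and 0.414). The plasmacytoid gene Siglech was higher by at least 2.23-fold in lysoDC and 5.78-fold in lysoMac. Of the 13 mast cell, basophil and eosinophil genes, limma called 0, and 0 had an unadjusted p under 0.05. Counts adjusted over the list alone (higher and lower) were 0 and 3 for epithelial and 1 and 4 for NK and innate lymphoid genes. They were 2 and 3 for B cell and 3 and 1 for T cell genes. In lysoDC they were 3 and 7 for plasmacytoid and 5 and 6 for type 1 dendritic cell genes. Among the 20 lists that were not shifted, the lowest adjusted p was 0.0741.

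In all, 1592 genes were higher and 1295 lower in lysoDC than in CD11b+ cDC by limma's moderated test, 704 and 464 of them by at least 1 on the log2 scale. Without CD11b+ cDC replicate 1, which carried epithelial transcripts, 1517 were higher and 1137 lower. The arrays of both populations did not overlap in 28.77% of the tested genes, where chance gives 10%.

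The comparison of lysoMac with CD11b+ cDC set a macrophage population with low MHC class II against the conventional dendritic cells. Among its increases was a proton pump subunit of lysosomes. Atp6v0d2 (transcript cluster 10511779) averaged 11.12 ± 0.19 (SD, n = 3) in lysoMac against 3.62 ± 0.26, at least 43.9-fold higher (adjusted p = 1.16e-07). Gpnmb was higher by at least 65.2-fold, Mmp2 59.5-fold, Cp 55.1-fold, Ms4a7 53.5-fold and Timp2 34.6-fold. Cd24a was 53.8-fold lower, and Pglyrp1 was lower by at least 45.3-fold, Itgae 39.0-fold, Klrd1 36.8-fold, Klri1 22.2-fold and P2ry10 12.9-fold. Adjusted p-values of these 12 genes were at most 0.000195.

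Of the 36 lists, 18 were shifted in lysoMac against CD11b+ cDC, 9 upward and 9 downward. With an estimated correlation 8 also passed, with adjusted p from 0.00181 (macrophage and dendritic cell core genes) to 0.0381 (type 2 dendritic cell genes). Macrophage core genes were higher for 30 of 36 members and lower for 0 (median 1.97, adjusted p = 4.48e-26), with Mertk higher by at least 3.94. Lysosome genes were higher for 28 of 38 and lower for 1 (adjusted p = 6.11e-17). Complement genes were higher for 9 of 15 and lower for 0 (adjusted p = 1.29e-07), with C5ar1 at least 30.0-fold, C1qb 30.2-fold and C1qa 29.7-fold higher. Iron and haem genes were higher for 11 of 15 and lower for 1 (adjusted p = 1.26e-07). These 4 lists passed with an estimated correlation. The remaining upward lists did not. Resident tissue macrophage genes were higher for 7 of 18 and lower for 1 (adjusted p = 0.0645 with an estimated correlation), with the fractalkine receptor Cx3cr1 (4.16 ± 0.16 SE) and Pf4 (at least 1.72) up and Hpgd (-3.63), which degrades prostaglandins, down. Interferon response genes were higher for 18 of 30 and lower for 3 (adjusted p = 0.206 with an estimated correlation), and Ifitm1 was 27.4-fold lower. Antimicrobial genes were higher for 7 of 19 and lower for 3 (adjusted p = 0.0913 with an estimated correlation), and matrix genes were higher for 8 of 22 and lower for 4 (adjusted p = 0.133 with an estimated correlation). Pattern recognition genes were higher for 14 of 25 and lower for 4 (adjusted p = 0.247 with an estimated correlation), and this call ended without lysoMac replicate 2 (camera adjusted p = 0.0652). On ranks the calls of pattern recognition (adjusted p = 0.126) and matrix genes (0.0965) ended. Adjusted over the list alone, the numbers higher and lower were 32 and 0 for macrophage core, 30 and 1 for lysosome, 10 and 0 for complement, 11 and 1 for iron and haem, 7 and 1 for resident macrophage, 20 and 3 for interferon response, 9 and 3 for antimicrobial, 9 and 5 for matrix and 14 and 5 for pattern recognition genes.

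Conventional dendritic cell core genes were lower in lysoMac for 24 of 28 members and higher for 0 (median -2.75, adjusted p = 1.59e-26), and the type 2 list was lower for 7 of 11 (adjusted p = 2.56e-08). Immediate early genes were lower for 16 of 18 (adjusted p = 1.89e-16), with Nr4a1 at least 21.5-fold and Btg2 9.14-fold lower. Proliferation genes were lower for 15 of 29 and higher for 1 (adjusted p = 1.25e-08), including the replication helicase genes Mcm4 (-2.04) and Mcm6 (-1.53). These 4 lists passed with an estimated correlation. MHC class II genes were lower for 8 of 11 and higher for 2 (median -1.89, adjusted p = 0.0747 with an estimated correlation). H2-Ob was 19.1-fold, H2-Oa 15.8-fold and Ciita 14.4-fold lower, in a population gated on low MHC class II; the gate gene H2-Ab1 is a member of this list. Ribosomal protein genes were lower for 13 of 20 (adjusted p = 0.0913 with an estimated correlation) and costimulation genes were lower for 8 of 20 and higher for 3 (adjusted p = 0.272 with an estimated correlation, and 0.0799 on ranks). NK and innate lymphoid genes were lower for 4 of 12 (adjusted p = 0.0913 with an estimated correlation). Of the epithelial list, Epcam, Cdh17 and Gp2 were lower by at least 3.80, 2.44 and 1.76 (adjusted p = 0.334 with an estimated correlation). The median change of that list was -0.74 with all arrays, -0.14 without CD11b+ cDC replicate 1, -1.19 without replicate 2 and -1.28 without replicate 3, and without the arrays numbered 1 its call ended (camera adjusted p = 0.0715). The numbers higher and lower, adjusted over the list alone, were 0 and 24 for the dendritic cell core, 0 and 9 for the type 2 list, 0 and 17 for immediate early, 1 and 16 for proliferation, 2 and 8 for MHC class II, 0 and 18 for ribosomal protein, 3 and 8 for costimulation, 0 and 5 for NK and innate lymphoid and 0 and 3 for epithelial genes.

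The heat shock list was not shifted against CD11b+ cDC in lysoMac (1 of 10 higher, 3 lower, adjusted p = 0.196) or in lysoDC (1 higher, 2 lower, adjusted p = 0.677). Bag3 was higher by 0.77 in lysoMac and 1.08 in lysoDC, and Hspa1a was lower by log2 -0.89 and -1.15. Oxidative phosphorylation genes passed for 1 of 27 in lysoMac and 2 in lysoDC. Chemotactic receptor genes moved both ways, with 6 of 22 higher and 7 lower in lysoMac and 5 higher and 7 lower in lysoDC. Cmklr1, the chemerin receptor, rose by log2 5.52 and 5.39 and P2ry14, a receptor for UDP-sugars, was at least 14.8-fold and 9.17-fold higher. Cytokine and chemokine genes were higher for 9 of 35 and lower for 6 in lysoMac, with Igf1 (at least 4.15), an insulin-like growth factor, and Il1a (4.52) up and Ccl22 (-3.91) down. In lysoDC 10 were higher and 6 lower, among them Il1a (4.65) and Il6, which fell by at least 2.30. Scavenger and apoptotic cell uptake genes were higher for 11 of 29 and lower for 6 in lysoMac and for 10 and 5 in lysoDC, with the scavenger receptor Msr1 35.1-fold and 38.6-fold higher. In the lipid list, 8 of 20 were higher and 4 lower in lysoMac (adjusted p = 0.0727). The classical monocyte list was not shifted (3 of 10 higher and 1 lower in lysoMac, 5 higher and 2 lower in lysoDC, adjusted p = 0.561 and 0.114). Its members diverged: Ccr2, the chemokine receptor of circulating monocytes, was 37.0-fold higher in lysoDC and 13.7-fold in lysoMac, Gda rose by log2 5.17 and 5.31, while Plac8 was 26.9-fold and 43.8-fold lower. The Ccr2 mean in CD11b+ cDC (5.69 ± 0.70 SD) lay only just above the median of all genes, so its folds are little firmer than bounds. In lysoMac, the numbers higher and lower adjusted over the list alone were 1 and 3 for heat shock, 0 and 0 for oxidative phosphorylation, 7 and 9 for chemotactic receptor, 12 and 6 for cytokine, 11 and 6 for uptake, 8 and 5 for lipid and 3 and 2 for monocyte genes. In lysoDC they were 1 and 2, 2 and 0, 6 and 9, 11 and 6, 10 and 7, 8 and 2, and 5 and 2 in the same order. By limma's moderated test, 1889 genes were higher and 1974 lower in lysoMac than in CD11b+ cDC, 839 and 649 of them by at least 1 on the log2 scale. Without CD11b+ cDC replicate 1, 1700 were higher and 1680 lower. Non-overlapping arrays made up 30.88% of genes, against 10% by chance.

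Both lyso populations departed from CD11b+ cDC in the same direction for most changed genes. The genes that passed in both comparisons and moved the same way numbered 2465, with 1332 higher and 1133 lower. Independent lists of these sizes would share 150.8 and 128.2. In 100 simulations, unchanged groups set against 3 simulated control arrays shared a mean of 0.01 and 0. No group was changed in those simulations, so hardly any gene could pass in either comparison. Their counts therefore do not show how many shared calls common controls add when both populations differ from them. Each gene was also drawn independently, so deviations common to many genes on the real control arrays are not covered. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.911 (0.502 simulated for shared controls), and their covariance was 0.372 against 0.0135 simulated, a difference of 0.358. With 3 control arrays the controls could not be split into groups of at least 2, and part of the excess may come from sharing them.

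**Figure D2:**
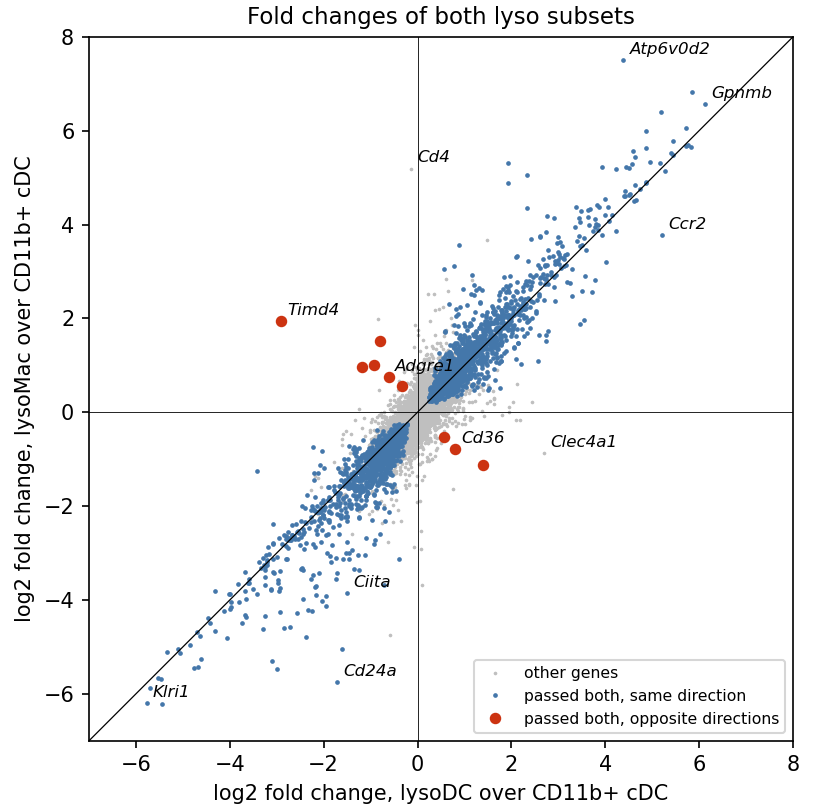
Log2 fold change over CD11b+ cDC in lysoDC (horizontal axis) and in lysoMac (vertical axis), one point per gene, with the diagonal marking equal change. Blue marks the 2465 genes that passed both tests in the same direction and red the 9 that passed in opposite directions; Cd4 and Atp6v0d2 lie far above the diagonal.

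The direct comparison of lysoMac with lysoDC gave fewer differences, 470 genes in all. Cd4, part of the gate, was 40.0-fold higher in lysoMac. Timd4, a phosphatidylserine receptor of resident macrophages (transcript cluster 10375472), was 29.0-fold higher at 10.57 ± 0.20 (SD, n = 3) against 5.71 ± 0.14 (log2 4.86 ± 0.21 SE, adjusted p = 1.91e-05). Its lysoDC mean lay only just above the median of all genes. Clec1b was 10.6-fold, Atp6v0d2 8.64-fold, Egfl6 7.80-fold and Wfdc17 7.09-fold higher. On the lower side, Emb, a basigin-family glycoprotein, was 18.0-fold lower in lysoMac, Cd24a 16.4-fold, the class II gene H2-Eb2 7.89-fold, Clec4a1 at least 8.59-fold, Clec4a4 at least 8.34-fold and Gpr141 at least 3.64-fold. Clec4a1 varied within populations (SD 1.12 in lysoMac and 0.96 in lysoDC), and its call ended without lysoDC replicate 1 (adjusted p = 0.0735) or replicate 2 (0.0898) and in the 6-array fit (0.0826).

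Of the 36 lists, 11 were shifted between lysoMac and lysoDC, 4 upward and 7 downward. With an estimated correlation 6 also passed, with adjusted p from 0.0138 to 0.0328. Proliferation genes were lower in lysoMac for 12 of 29 members and higher for 0 (median -0.63, adjusted p = 4.45e-23, and 0.0138 with an estimated correlation), with the ubiquitin-conjugating enzyme gene Ube2c at -1.30 and the cyclin gene Ccna2 at -1.29. MHC class II genes were lower for 7 of 11 and higher for 0 (median -1.33, adjusted p = 2.24e-13), with H2-Eb1 6.01-fold, Ciita 5.10-fold and H2-Aa 3.85-fold lower, in populations whose gates differed in MHC class II. Conventional dendritic cell core genes were lower for 7 of 28 (adjusted p = 1.58e-07), and immediate early genes for 4 of 18 (adjusted p = 2.8e-12), Btg2 by log2 -1.36, Fos by -1.15 and Egr1 by -0.77. Macrophage core genes were higher for 6 of 36 (adjusted p = 7.03e-06), Pecr among them at 1.21, and resident macrophage genes for 3 of 18, namely Timd4, Pf4 (at least 1.72) and Adgre1 (1.36), which encodes F4/80 (adjusted p = 0.000224). These 6 lists passed with an estimated correlation. Counts adjusted over the list alone (higher and lower) were 0 and 20 for proliferation, 1 and 7 for MHC class II, 1 and 10 for the dendritic cell core, 0 and 11 for immediate early, 11 and 1 for macrophage core and 5 and 0 for resident macrophage genes.

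With the preset correlation alone, 5 lists passed between lysoMac and lysoDC. Iron and haem genes were higher for 3 of 15 and lower for 1 (adjusted p = 0.0576 with an estimated correlation), with the iron exporter gene Slc40a1 at least 1.96-fold higher and the transferrin receptor gene Tfrc 2.74-fold lower. Lysosome genes were higher for 3 of 38 (adjusted p = 0.303 with an estimated correlation), and the type 2 dendritic cell list was lower for 3 of 11 (adjusted p = 0.303 with an estimated correlation, 0.0857 on ranks and 0.0609 with fry). Of 20 ribosomal protein genes limma called 0, with 6 lower at an unadjusted p under 0.05 (list adjusted p = 0.000224, and adjusted p = 0.311 with an estimated correlation). That call also ended with dim genes left out (0.108), with repeated quantile normalization (0.0708) and with fry (0.0863). Cytokine genes were higher for 2 of 35 and lower for 3, with Igf1 at 2.71, Ccl3 at 1.92 and Ccl22 at -1.97 (adjusted p = 0.301 with an estimated correlation). The cytokine list's camera adjusted p of 0.0298 became 0.0616 without lysoMac replicate 1, 0.209 without lysoMac replicate 3, 0.0914 without lysoDC replicate 1 and 0.0884 without lysoDC replicate 2. It was 0.551 with dim genes left out, 0.13 with repeated quantile normalization, 0.0829 with median centring, 0.0775 without the arrays numbered 1, 0.0575 on ranks and 0.149 with fry. Adjusted over the list alone, the numbers higher and lower were 6 and 1 for iron and haem, 7 and 1 for lysosome, 1 and 3 for the type 2 list, 0 and 0 for ribosomal protein and 3 and 9 for cytokine genes. Outside the shifted lists, the complement gene C2 (2.35), Apoc1 (2.02), Cd180 (1.69) and Timp2 (1.14) were higher in lysoMac, and Ifitm1 (-2.39), Il1r2 (-2.15), Adam8 (-1.51) and the classical monocyte gene Hp (-1.94) were lower.

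In all, 180 genes were higher and 290 lower in lysoMac than in lysoDC by limma's moderated test, 71 and 121 of them by at least 1 on the log2 scale, and arrays did not overlap in 15.88% of genes against 10% by chance. These counts fell to 81 and 174 without lysoDC replicate 1, to 70 and 125 without lysoDC replicate 2 and to 91 and 160 without lysoDC replicate 3. Without the arrays numbered 1 they were 62 and 90, and the calls of Cd24a, Pf4, Slc40a1, Tfrc, Ube2c, Ccna2, Fos, Egr1, Pecr, Ccl3, Apoc1, Timp2, Adam8, Il1r2, Ifitm1, Hp and Clec4a1 were lost, with adjusted p from 0.0593 to 0.172.

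**Figure D3:**
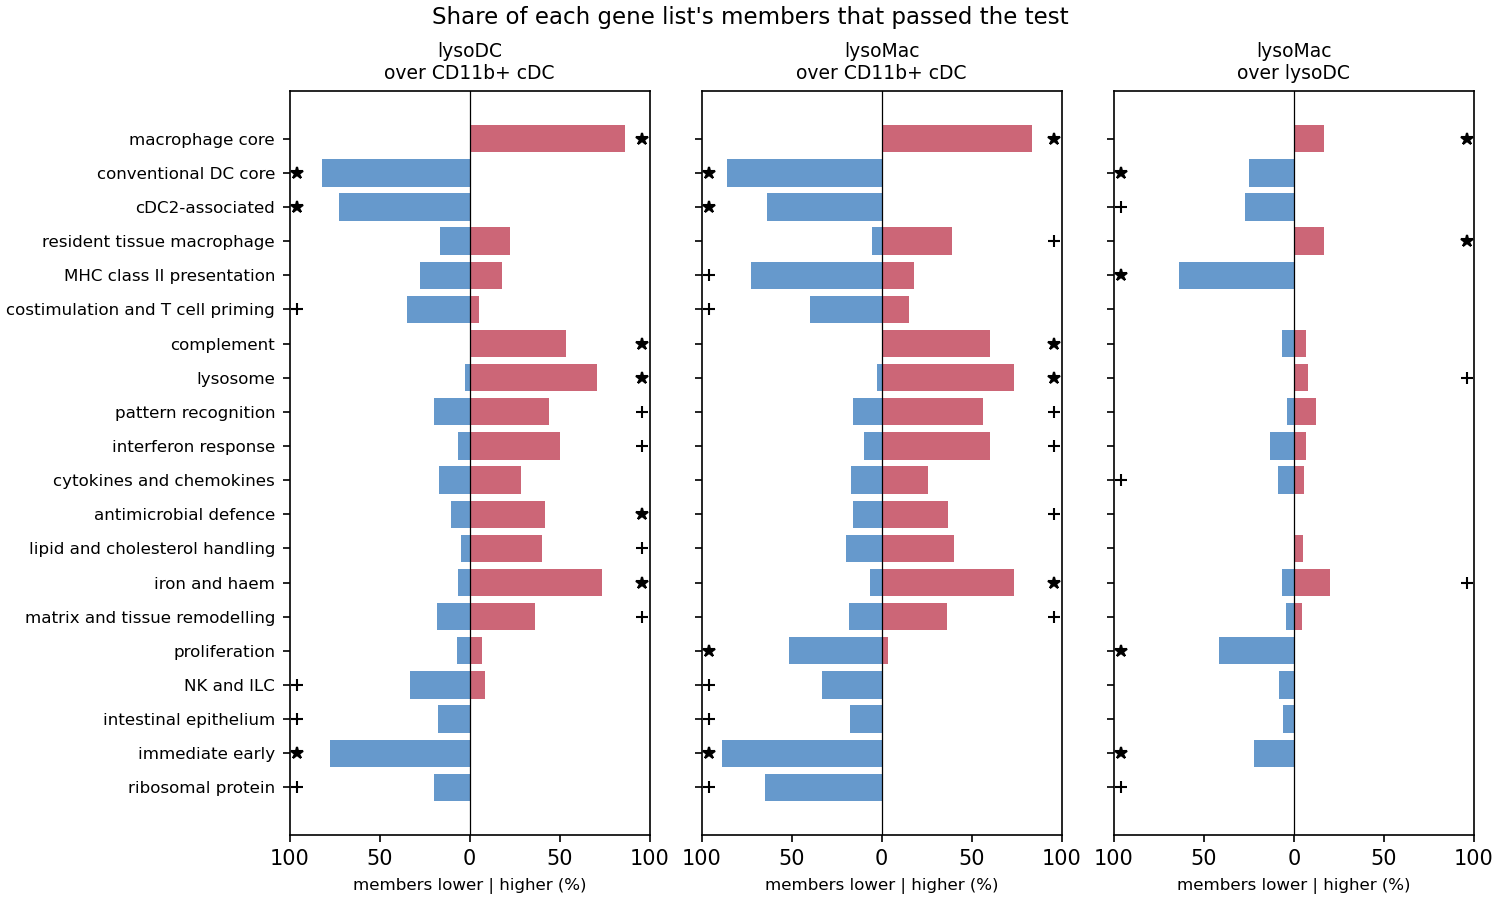
Percentage of each list's measured members that passed the test higher (red, right) or lower (blue, left) in the 3 comparisons, for the 20 lists shifted in at least 1 of them. Stars mark lists that passed camera with the preset and the estimated correlation and plus signs those that passed with the preset one alone; in lysoMac against lysoDC the proliferation and MHC class II lists have members lower and 0 higher, and in lysoMac against CD11b+ cDC they have members both ways, most of them lower.

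Genes highest in a single population numbered 409 in CD11b+ cDC, 27 in lysoDC and 60 in lysoMac. Klri1, P2ry10, Pglyrp1, Klrd1 and Itgae were the CD11b+ cDC genes taken by the naming rule. LysoDC had Clec4a1, which averaged 9.11 ± 0.96 (SD, n = 3) against 6.41 ± 0.41 in CD11b+ cDC and 5.54 ± 1.12 in lysoMac, then Gria3, Tdgf1, Hp, the haptoglobin gene, and Nid1, which encodes a basement membrane protein. Gria3, a glutamate receptor subunit gene, averaged 7.39 ± 0.08 in lysoDC, 4.95 ± 0.05 in CD11b+ cDC and 5.17 ± 0.14 in lysoMac. The difference of Clec4a1 between lysoDC and CD11b+ cDC did not pass without CD11b+ cDC replicate 2 (adjusted p = 0.0529) or replicate 3 (0.0662), or without lysoDC replicate 1 (0.0587) or replicate 2 (0.0526). LysoMac had Cd4, Clec1b, Atp6v0d2, Egfl6 and Igf1. Igf1 averaged 4.77 ± 0.26 in CD11b+ cDC, 7.10 ± 0.22 in lysoDC and 9.82 ± 0.07 in lysoMac. Without the arrays numbered 1, 13 genes were highest in lysoDC and 38 in lysoMac.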

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

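The tests of the 3 patterns weighed here, other than the counts of splits, were chosen after the results were seen.

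Opposite changes against CD11b+ cDC were seen in 9 genes that passed in both lyso populations. The direct difference between lysoMac and lysoDC passed for each. It is the difference of those 2 changes in the same fit, so its passing follows from the selection and is not separate support. Timd4 was lower in lysoDC (-2.91) and higher in lysoMac (1.95), and the same held for Ly9 (-0.79 and 1.52), Trp53i11 (-1.19 and 0.97), Ccl3 (-0.92 and 1.00), Adgre1 (-0.61 and 0.76) and Agpat3 (lower by at least 0.22, and 0.57). Clec4a2 (1.40 and -1.12), Cd36 (0.80, and lower by at least 0.66) and Anln (at least 0.49 in lysoDC) went the other way. The Anln means of lysoMac (5.06) and CD11b+ cDC (5.59) were both under the median of all genes, so the size of that fall is not given. The 9 genes were named after their values were seen. Some calls against CD11b+ cDC ended without a single array: Adgre1 in lysoDC without any CD11b+ cDC or lysoDC array (adjusted p from 0.0673 to 0.132), and Agpat3 in lysoDC without any CD11b+ cDC array or lysoDC replicate 1 or 3 (0.0507 to 0.0797). The call of Ccl3 in lysoDC ended without any CD11b+ cDC array, lysoDC replicate 1 or 3 or lysoMac replicate 1 (0.0508 to 0.156), and in lysoMac without any CD11b+ cDC array (0.0525 to 0.0736). The call of Clec4a2 in lysoMac ended without CD11b+ cDC replicate 1 or 2 or lysoMac replicate 2 or 3 (0.0511 to 0.0861). Without the arrays numbered 1, the direct difference ended for Clec4a2 (0.0507), Trp53i11 (0.0668) and Ccl3 (0.111). In lysoDC the calls of Trp53i11 (0.0597), Clec4a2 (0.0803), Agpat3 (0.136) and Ccl3 (0.277) ended with those arrays left out, and in lysoMac those of Cd36 (0.0546), Clec4a2 (0.0557), Anln (0.0656), Ccl3 (0.104) and Trp53i11 (0.143).

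Signal outside the named genes was seen in the 13767 clusters without a single gene symbol: 155 were higher and 123 lower in lysoDC than in CD11b+ cDC, and 222 were higher and 347 lower in lysoMac. These were 2.02% and 4.13% of such clusters, a lower share than the 14.48% and 19.4% of the 19938 genes. Between lysoMac and lysoDC, 2 were higher and 6 lower, or 0.0581%.

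Epcam, Cdh17 and Gp2, from a list of epithelial genes, were higher in CD11b+ cDC than in lysoDC and lysoMac. Epithelial RNA was present on CD11b+ cDC replicate 1, where Reg3g reached 9.98 and Fabp1 10.1, although the gate on high CD11c and MHC class II was meant to remove such cells. In the mean of replicates 2 and 3 the highest excess of the other 14 genes of the list over lysoDC or lysoMac was 0.803, but on replicate 2 alone Tff3 exceeded the lower of them by 1.61, so a trace of epithelial RNA there is not excluded. With values under the median of all genes raised to it, Epcam, Cdh17 and Gp2 exceeded both lyso means by at least 1.93 on replicate 2 and 1.46 on replicate 3. The other 14 reached at most 0.06 on replicate 3, where a gene under the median could not show an excess. Without raised values they reached at most 0.23 there, against at least 3.21 for the 3 genes. This test, which followed an earlier one that rested on replicate 1 alone, argues against epithelial RNA as the source of the difference in these 3 genes. A candidate explanation, not tested further, is that CD11b+ cDC transcribe these 3 genes themselves.

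Cd79b, Cd6 and Icos were higher in both lyso populations. RNA of B or T cells, carried over or engulfed, would raise Cd79a, Ms4a1, Ighm, Cd3d, Cd3e, Cd3g and Lat as well. Ms4a1, Cd3d, Cd3g and Lat averaged under the median of all genes in each population, so they are not weighed. Log2 changes in lysoDC and lysoMac were -0.17 and -1 for Cd79a (SE 0.33) and -0.98 and -1.71 for Ighm (SE 0.69). For Cd3e they were -0.36 and -0.09. No change of Cd79a or Ighm passed, and Ighm varied among the CD11b+ cDC arrays (SD 1.41). Cd79b itself rose by 2.84 and 2.93. Germinal centre B cell genes were higher for 4 of 8 and lower for 1 in lysoDC, and 3 and 1 in lysoMac. That list was not shifted (camera adjusted p = 0.267 and 0.255). In lysoMac, 2 of 17 B cell genes were higher and 4 lower. Cd79a and Ighm did not rise with Cd79b, which argues against B cell RNA as its source. T cell RNA as the source of Cd6 and Icos is not settled, because Cd3e, at 5.74 to 6.1, lay close to the median of all genes. Cross-hybridisation of single probes was not testable from summarised values, so transcription of these genes in lyso cells remains a hypothesis.

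Immediate early genes were lower in both lyso populations. Stress during dissociation or sorting that was stronger in CD11b+ cDC cannot be told apart from a difference between the populations: the heat shock list had a median of -0.061 in lysoMac against CD11b+ cDC, with members going both ways. Epithelial RNA on CD11b+ cDC replicate 1 is argued against as the source, because the median of the immediate early list without that array was -0.956 in lysoDC and -1.42 in lysoMac, against -1.003 and -1.471 with it. A difference between the populations themselves stays open.

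Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of the splits, the real one, gave as many genes: 2887 for lysoDC against CD11b+ cDC, 3863 for lysoMac against CD11b+ cDC and 470 for lysoMac against lysoDC, with 0 genes as the highest other count in each. For gene lists the real split gave 16, 18 and 11, and the highest other splits 12, 11 and 8. For genes highest in CD11b+ cDC, lysoDC and lysoMac, 100 of the 840 splits of the 9 arrays were drawn and 1 of them, the real one, gave as many, with 409, 27 and 60 genes against 13, 12 and 13 at most in another split. For the genes that moved the same way, the real split gave 2465 and the highest other 39. Splits that mix populations put the differences between them into the spread within groups, which lowers their counts. The drawn splits therefore cannot exclude chance for these 4 counts.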

How the results depend on the processing

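Leaving out the arrays numbered 1 was the alternative chosen after seeing the data; the others were planned. No list or named gene reversed its direction. More genes were lower (1974) than higher (1889) in lysoMac than in CD11b+ cDC, but this balance turned at an adjusted p under 0.01 (1186 and 1292), with a log2 change of at least 1, in the 6-array fit (1560 and 1563), without the arrays numbered 1 (1370 and 1495), and without CD11b+ cDC replicate 1 (1680 and 1700) or 2 (1395 and 1553) or lysoMac replicate 1 (1716 and 1783) or 3 (1643 and 1676). The 6-array fit gave 189 genes lower in lysoMac than in lysoDC, and testing all clusters gave 93 higher and 154 lower there. At an adjusted p under 0.01, 732 genes were lower in lysoDC and 1186 in lysoMac than in CD11b+ cDC, 66 were higher and 112 lower in lysoMac than in lysoDC, 16 were highest in lysoDC and 1600 moved the same way. Requiring a log2 change of at least 1 left 704 and 464, 839 and 649, 71 and 121, and 1014 that moved the same way; a stricter threshold passes fewer genes by construction. Without the arrays numbered 1, 62 were higher and 90 lower in lysoMac than in lysoDC, 13 were highest in lysoDC and 38 in lysoMac; with 2 arrays a group the test has fewer samples. Camera with an estimated correlation passed 8, 8 and 6 lists, and fry, which tests a list on its own and not against other genes, 25 for lysoDC and 28 for lysoMac against CD11b+ cDC. Leaving out single arrays gave 70 to 174 genes higher and 125 to 284 lower in lysoMac than in lysoDC, 18 to 26 highest in lysoDC and 47 to 65 in lysoMac. Where not stated, the cause was not tested. Of 294 passing values of named genes, 66 were lost without the arrays numbered 1, at most 29 without any single array and at most 20 under any other setting. Of 45 list calls, 23 were lost with an estimated correlation, 9 on ranks and at most 3 under any other setting. Rescaling moved the median of all genes by at most 0.0262 in size. Same-numbered arrays of different populations had deviations that correlated at 0.012 to 0.273 in 9 pairs (median 0.135), and arrays with other numbers at -0.225 to 0.074 in 18 pairs (median -0.061). The samples were not treated as paired, because the labels do not say that a number marks an experiment. Deviations were taken from each population's mean, so positive correlations of same-numbered arrays make the others negative. The overlap of the ranges is therefore not evidence against pairing. A shared experiment is not excluded: 7 of 9 arrays correlated best with their own number in both other populations. With the number as a fixed block, 11 of 294 passing values of named genes and 0 of 45 list calls were lost. With the replicate number as a block, 1676 genes were higher and 1498 lower in lysoDC and 2020 and 2257 in lysoMac than in CD11b+ cDC, and 169 and 273 in lysoMac than in lysoDC. With few arrays and no detection call, small changes and genes near the lowest intensities are the least certain.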

Other observations

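Gene families defined by the stem of their symbols were tested after the data were seen. There were 326 families with at least 5 members above the median of all values on at least 3 arrays. More families passed with the preset correlation than are given here, and the choice followed no fixed rule. Guanylate-binding protein genes (Gbp), which encode interferon-induced defence proteins, were higher for 7 of 7 members in lysoDC (median 1.58, camera adjusted p = 1.37e-06) and in lysoMac (median 1.64, adjusted p = 2e-05) against CD11b+ cDC. Toll-like receptor genes (Tlr) were higher for 7 of 10 members and lower for 2 in lysoDC (median 1.03) and higher for 8 in lysoMac (median 1.15). Genes with the stem Pla were higher for 5 of 7 in lysoDC and 6 in lysoMac. Lipoprotein receptor genes (Lrp) were higher for 4 of 6 in lysoDC and 5 in lysoMac. Mannosidase and related genes (Man) were higher for 5 of 9 and 6. With an estimated correlation none of these families passed, with adjusted p = 0.344 in lysoDC and 0.349 in lysoMac.

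On the lower side, large-subunit ribosomal protein genes (Rpl) were lower for 6 of 34 in lysoDC (median -0.22) and 24 of 34 in lysoMac (median -0.32), splicing factor genes (Srsf) for 5 of 9 and 7, and regulators of G-protein signalling (Rgs) for 4 of 8 and 5. Interferon-induced transmembrane genes (Ifitm) were lower for 4 of 6 in lysoMac (median -1.27), opposite to the Gbp genes. Genes with the stem Ifi were higher there for 6 of 12 and lower for 0 (median 1.07). Estimated-correlation adjusted p-values of these families lay between 0.344 and 0.455. Some Gbp, Tlr, Rpl and Ifitm genes also belong to the fixed lists above, so these families are not separate evidence.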
